A study of Oryzias latipes with 15 samples.

How the data were processed

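RNA was measured in testis of medaka, Oryzias latipes, a small egg-laying fish used in toxicology, in 15 libraries of 5 groups with 3 biological replicates each. Per the labels, the groups were a control, 0.01 mg/L potassium perchlorate (the low dose), 10 mg/L potassium perchlorate (the high dose), 10 mg/L potassium perchlorate with 3 mg/L vitamin C, and 3 mg/L vitamin C alone. Perchlorate blocks iodide uptake into the thyroid, and vitamin C is an antioxidant. Per the labels' protocols, total RNA was extracted with a ZR-Duet DNA/RNA MiniPrep kit and libraries were made with the NEBNext Ultra II RNA kit. The labels name no batch or date, and the sources used here do not say whether a replicate was 1 fish or a pool of fish.

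Per the submitters' processing notes, the authors used fastp 0.23.2, STAR 2.7.7a and DESeq2 1.34.0. The genome build, the counting step, its strand setting and its handling of reads that match several genes are not given in the sources used here. Values of near-identical gene copies, such as egg coat, keratin and protease genes, and of genes with an overlapping or antisense partner are uncertain for that reason. The deposited table holds a signal per gene and library, a normalized read count with no unit of its own, for 23028 genes. Of these, 13541 have a symbol in the deposited table. No coordinates are given here, because the build is not given in the sources used here.

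Each library's values were whole multiples of its smallest value above 0. Dividing by that step gave whole reads for 100% of 345420 values, within 0.001 of a whole number. The steps were the reciprocals of the size factors that DESeq2's median of ratios gives for the recovered reads. The recovered totals gave the depth of each library, from 3.21 to 21.3 M reads. Shallower libraries carry more counting error, so the high-dose replicate with 3.21 M reads is the least precise. No pair of replicates agreed within sampling noise: the chi-square per degree of freedom lay between 3.42 and 142, so all 15 libraries were counted as separate replicates.

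The main test was limma 3.58.1 with a mean-variance trend on log2(value + 1), in R 4.3.3, with 1 fit over all 15 libraries. It covered the 17778 genes with a mean of at least 10 over the libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, over the genes of each of 8 contrasts. A fold change is on the log2(value + 1) scale, which understates the change of low genes, and is given ± its standard error from the fit with n = 3 libraries per group. The fit gives each gene 1 spread for all groups. Standard errors and p can thus be too small for a more variable group, such as the low dose, and too large for a less variable one. Group values are means ± SD, n = 3. In data simulated for the high dose against control over 17778 genes, the test recovered 2.99% of genes changed 1.5-fold, 29.9% of those changed 2-fold and 95.5% of those changed 4-fold, and 6 of its 91 calls were false. There 67, 67 and 66 genes were changed by these folds, far fewer than the 6886 called in the real comparison. The adjusted threshold was therefore stricter in the simulated data.

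For each contrast, camera tested 30 gene lists written before the data were examined, with a preset correlation between genes of 0.01 and adjustment over the lists, and again with an estimated correlation. Lists needed at least 5 tested members. Genes to be named were chosen by a rule set before the data were examined. The rule took the 8 largest rises and the 8 largest falls among called genes with a symbol and a mean of at least 50 whose replicates did not overlap, without that last condition in the interaction contrast. It added up to 4 called members of each list with the smallest adjusted p, and a fixed panel of endocrine, germ cell, antioxidant and methylation genes in every contrast. The text names a part of these genes, picked after their values were seen, and 1 result is not reported here. Where 2 entries share a symbol, the identifier is given.

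A held-out score summarised the high-dose response. It used the 200 genes with the smallest p for the high dose against control, in 9 rounds that each left 1 control and 1 high-dose library out of the choice of genes. Control and high-dose libraries were scored only when left out. The score is the mean signed log2 value, relative to the left-out controls, and groups were compared by an exact 2-sided permutation test. Whether replicate numbers pair the samples was read from the data, as the labels do not say: the values of same-numbered libraries, relative to their group means, were correlated. For the high dose with and without vitamin C the 3 pairs gave 0.361, 0.198 and 0.124, all above the bound of 0.1, so the fit with a replicate block is given beside the results it changes there. In no other 2 groups did all 3 pairs exceed it. Fold changes that share control libraries were set against 100 simulated sets of unchanged groups.

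Alternative settings fixed before the files were opened changed the pseudocount, the filter on low values, the scaling (TMM and quantile normalization), the libraries in the fit, the trend, the threshold and the replicate block, left out each library in turn, and used edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. After seeing the data, 7 alternatives were added. They left out the low-dose libraries, from the fits and from the choice of the genes of the score, left out low-dose replicates 1 and 2, and thinned every library to the smallest total. The others took S6 kinase genes out of the ribosome list and islet hormone genes out of the pancreas list, and scaled all libraries on genes with a control mean of at least 500. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.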

Results

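Testis RNA of medaka was sequenced in 15 libraries, 3 for each of 5 groups. The 5 groups were control fish, fish exposed to 0.01 mg/L or 10 mg/L potassium perchlorate, fish given 10 mg/L perchlorate with 3 mg/L vitamin C, and fish given 3 mg/L vitamin C alone. The series was made to ask how perchlorate alters the testis and whether vitamin C changes that response. Control libraries held 7.82 to 13.0 M reads, low-dose libraries 5.48 to 6.19 M and high-dose libraries 3.21 to 12.2 M. Libraries of the high dose with vitamin C held 10.5 to 21.3 M reads, and those of vitamin C alone 7.86 to 15.04 M. The first principal component held 49.7% of the variance, and the 3 low-dose libraries lay at 42.8, 137 and 201 on it, above every other library. The second component held 25.7% and separated the high-dose libraries, at 49.1 to 121, from the controls, at -75.7 to -30.3.

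**Figure D1:**
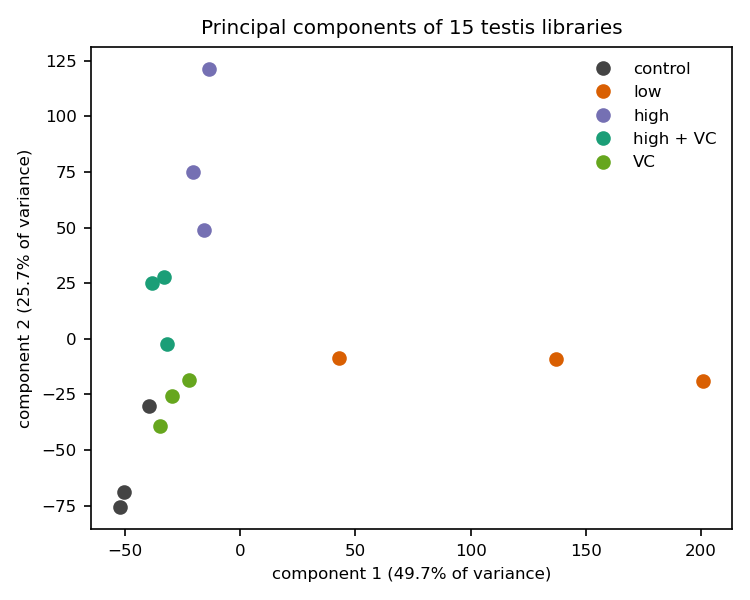
Principal components of log2 values in 15 testis libraries, component 1 on the x axis and component 2 on the y axis, in units of the component scores. Each point is a library, coloured by group, and the low-dose libraries lie at 42.8, 137 and 201 on component 1.

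The low dose was compared with control to ask what 0.01 mg/L perchlorate changed in the testis. Egg coat and oocyte genes were far higher. zp3b (ENSORLG00000016064), an egg coat glycoprotein gene, rose from 25.0 ± 6.39 to 10034 ± 6919 normalized counts, a log2 fold change of 8.24 ± 0.47 (limma adjusted p = 1.49e-08). bmp15, an oocyte growth factor gene, rose from 7.19 ± 2.52 to 5137 ± 3833 (log2 fold change 8.89 ± 0.55). Several genes of sperm tails and of meiosis were lower, among them tekt2, a sperm tail filament gene, from 1217 ± 210.2 to 541 ± 217 (log2 fold change -1.24 ± 0.26, limma adjusted p = 0.00181). The rise was uneven between the libraries: zp3b stood at 11509.5, 16096 and 2496 in low-dose replicates 1, 2 and 3, and at 21.2, 32.4 and 21.4 in the controls. The standard errors come from a spread shared over all groups, so they can understate the error of such uneven changes.

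Of 14 oocyte genes in the list, 12 rose, 1 fell and 1 did not pass (camera adjusted p = 1.83e-07), with a median log2 fold change of 5.03. With an estimated correlation neither this list nor any other of the 30 passed in this comparison, the smallest being an adjusted p = 0.929 with an estimated correlation. zar1, a maternal effect gene, rose by 7.65 ± 0.47 on the log2 scale and org by 7.16 ± 0.49. Outside the list, the largest rises included zp3f.1 (8.95 ± 0.63), another egg coat gene, birc5b (8.90 ± 0.64), a survivin gene of cell division, slc7a6 (8.70 ± 0.56), an amino acid transporter gene, ctss (8.67 ± 0.61), a lysosomal protease gene, and alv (8.63 ± 0.47). nqo1, a quinone reductase gene, went from 83.6 ± 2.20 to 42247 ± 35127 (log2 fold change 8.48 ± 0.51). The early germ cell genes nanos3 (5.08 ± 0.65) and pou5f3 (6.63 ± 0.68), the estrogen-forming enzyme gene hsd17b1 (5.13 ± 0.64), the cyclin gene ccne1 (2.71 ± 0.45) and the epithelial adhesion gene epcam (3.30 ± 0.39) rose as well. nanos3 and pou5f3 belong to the spermatogonia list of 22 genes, which was not called. Its mean log2 difference from the control mean was 0.678 ± 0.169, while its share of reads was 0.292% ± 0.102 against 0.435% ± 0.00609 in the controls. slc5a5, the iodide transporter that perchlorate blocks, rose from 268 ± 8.91 to 1007 ± 643 (log2 fold change 1.69 ± 0.34, limma adjusted p = 0.00133).

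Of 38 spermatid and sperm genes, 0 rose, 33 fell and 5 did not pass (1 rose and 35 fell adjusted over the list alone), with a median of -1.11 and a camera adjusted p of 8.94e-09. DNAH5, a dynein gene, changed by -1.63 ± 0.31, and CFAP43, a flagellum gene, by -1.72 ± 0.31. Of 19 meiosis genes, 0 rose, 14 fell and 5 did not pass, with a median of -0.99 (camera adjusted p = 1.24e-04). They included HFM1, a crossover helicase gene (-2.65 ± 0.48), dmc1, a strand exchange gene (-1.16 ± 0.26), and the meiotic cohesin genes rad21l1 (-1.38 ± 0.26) and smc1b (-1.46 ± 0.30). The spermatid and sperm score was -0.92, -1.88 and -0.38 in low-dose replicates 1, 2 and 3, and the oocyte score was 4.79, 5.25 and 3.23 in the same libraries, in mean log2 units from the control mean. The sperm score was thus lowest where the oocyte score was highest. Whether oocyte RNA only lowered the share of testis RNA, and with it the values of testis genes, was not tested. The Sertoli cell list did not pass (camera adjusted p = 0.818; test down, median -0.19, mean 0.00), and of its 26 genes 5 rose, 7 fell and 14 did not pass. Single genes of testis somatic cells were lower: amh (ENSORLG00000015951), a Sertoli cell hormone gene, changed by -1.56 ± 0.27, dmrt1, a male sex factor gene, by -1.38 ± 0.38, and the gonadotropin receptor genes fshr and lhcgr by -0.80 ± 0.24 and -1.16 ± 0.31. The other amh entry (ENSORLG00000005044) stood at 383 ± 112 normalized counts at the low dose and 381 ± 59.5 in the controls. The monocarboxylate transporter gene slc16a3b changed by -3.74 ± 0.72 and the DNA demethylation gene TET1 by -1.23 ± 0.30.

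Of 74 nuclear genes of oxidative phosphorylation, 36 rose, 5 fell and 33 did not pass (camera adjusted p = 0.0017), with uqcr10 up by 2.15 ± 0.40. Of 13 genes of the mitochondrial genome, 0 rose, 7 fell and 6 did not pass (camera adjusted p = 0.0141), with ND5 at -1.60 ± 0.43. Of 73 genes in the cytosolic ribosome list, 31 rose, 6 fell and 36 did not pass (camera adjusted p = 0.00782), with rpl28 up by 1.35 ± 0.29. The name pattern of this list also took in 9 genes of ribosomal S6 kinases, which are not ribosomal proteins. Without them, an alternative chosen after seeing the data, 28 rose, 2 fell and 34 did not pass of 64 (camera adjusted p = 0.00133). The antioxidant list was not called (camera adjusted p = 0.0727), although 21 rose, 6 fell and 31 did not pass of its 58 members. The steroid hormone list (camera adjusted p = 0.664; 6 rose, 4 fell and 15 did not pass) and the thyroid axis list (camera adjusted p = 0.499; 3 rose, 4 fell and 13 did not pass) were not called either. Of the panel, star (-0.35 ± 0.27), a cholesterol carrier gene of steroid synthesis, the antioxidant enzyme genes sod1 (0.25 ± 0.21) and cat (0.09 ± 0.15) and the DNA methyltransferase gene dnmt1 (0.56 ± 0.24, limma adjusted p = 0.0644) did not pass.

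In all, 4423 genes were higher and 4076 lower at the low dose, and 3472 higher and 4856 lower with quantile normalization. With only these 2 groups in the fit far fewer genes were called. Then 5 of the 32 called genes named in the text for this comparison lost their call. Scaling on genes with a control mean of at least 500, chosen after seeing the data, gave 6029 higher and 2517 lower. It gave calls to dnmt1, cat and sod1 and ended that of fshr. Without low-dose replicates 1 and 2, an alternative chosen after seeing the data that treats the remaining library as varying like the other groups, 792 were higher and 421 lower. Then 9 of the 14 oocyte genes still rose, while 1 of the 38 spermatid and sperm genes and 1 of the 19 meiosis genes fell. The calls of tekt2, CFAP43, dmc1, rad21l1, smc1b, amh, dmrt1, fshr, lhcgr, TET1, slc16a3b, slc5a5, ND5, uqcr10 and rpl28 were lost. The mitochondrial genome list lost its call without control replicate 3 or low-dose replicate 2, and the ribosome list without low-dose replicate 3 and with quantile normalization.

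**Figure D2:**
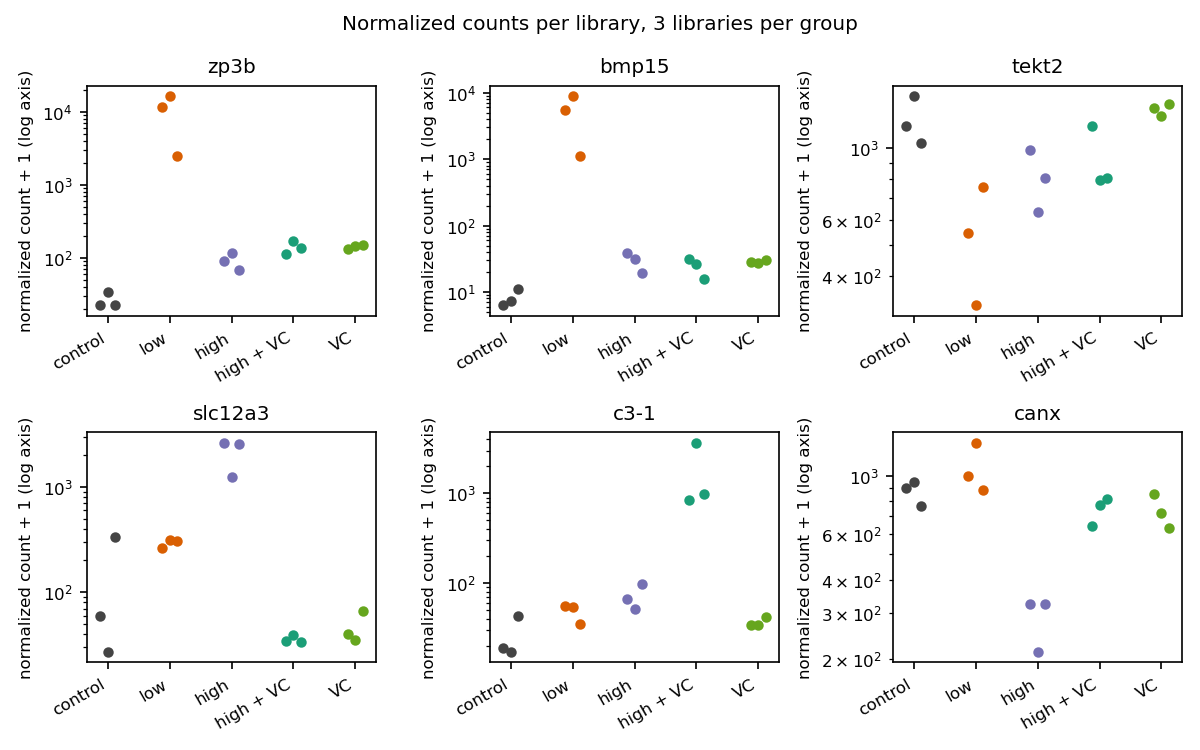
Normalized counts plus 1 (y axis, log scale) of 6 genes in each of the 15 libraries, 3 points per group, groups on the x axis (low, 0.01 mg/L perchlorate; high, 10 mg/L perchlorate; VC, vitamin C). zp3b was 2496 or more in the low-dose libraries and at most 32.4 in the controls, and slc12a3 was 1228 or more in the high-dose libraries and at most 329.7 in the controls.

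The high dose was compared with control to ask what 10 mg/L perchlorate changed. The largest rises included genes of epithelial transport and digestive enzymes. slc12a3 (ENSORLG00000000412), a sodium chloride transporter gene of kidney epithelium, rose from 138 ± 167 to 2128 ± 780.0 normalized counts (log2 fold change 4.63 ± 0.61, limma adjusted p = 9.86e-05), although control replicate 3 stood at 329.7 against 58.3 and 26.2 in the others. Camera called the DNA repair and epigenetic enzyme lists lower, with part of their genes called, but neither passed when the correlation was estimated (adjusted p = 0.587 with an estimated correlation for both). sos2 (ENSORLG00000009137), a guanine nucleotide exchange factor gene, fell from 823 ± 105 to 119.9 ± 33.8 (log2 fold change -2.80 ± 0.30, limma adjusted p = 5.56e-05).

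Of 62 DNA repair genes, 0 rose, 33 fell and 29 did not pass (1 rose and 34 fell adjusted over the list alone), with a median of -0.48 and a camera adjusted p of 2.36e-05. Neither this list nor any other passed here with an estimated correlation, where the smallest was an adjusted p = 0.587 with an estimated correlation. exo1, a DNA end resection gene, changed by -1.28 ± 0.18, rad54l, a recombination gene, by -1.07 ± 0.18, and the ligase gene lig1 by -0.83 ± 0.15. Of 82 genes of epigenetic enzymes, 2 rose, 31 fell and 49 did not pass, with a median of -0.39 (camera adjusted p = 2.46e-04). The median of all 4696 genes with a control mean of at least 500 was -0.37, close to those of both lists. KMT2E changed by -1.85 ± 0.24, the histone H3K27 methyltransferase gene ezh2 by -1.28 ± 0.19, the histone demethylase gene kdm5c by -1.27 ± 0.15, and dnmt1 by -0.98 ± 0.24. Of 48 cell cycle genes, 3 rose, 17 fell and 28 did not pass (camera adjusted p = 0.00564), with cdk2 at -1.35 ± 0.19 and the centriole kinase gene plk4 at -1.59 ± 0.26. Of 37 heat shock and protein folding genes, 0 rose, 14 fell and 23 did not pass (camera adjusted p = 0.00564), with the chaperone gene canx from 867 ± 93.6 to 285 ± 63.6 (-1.62 ± 0.20) and sel1l at -1.09 ± 0.16. Of 19 meiosis genes, 0 rose, 7 fell and 12 did not pass (camera adjusted p = 0.0226), with HFM1 at -2.49 ± 0.48, rad21l1 at -1.22 ± 0.26 and rec8b at -1.15 ± 0.30. Spermatid and sperm genes had a median of -0.37, and 0 rose, 7 fell and 31 did not pass, a list change that did not pass (camera adjusted p = 0.0577). It did without control replicate 3 (camera adjusted p = 0.0257) or high-dose replicate 1 (camera adjusted p = 0.017). Other large falls were BIRC6 (-2.49 ± 0.33), an apoptosis inhibitor gene, the mRNA 3' end processing gene cpsf1 (-2.54 ± 0.28) and the kinase gene TAOK2 (-2.49 ± 0.40). amh (ENSORLG00000015951) changed by -1.48 ± 0.27 and the germ cell helicase gene ddx4 by -0.62 ± 0.18, a call lost when control replicate 1 or 2 was left out.

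Of 15 pancreas genes, 4 of them islet hormone genes, 12 rose, 0 fell and 3 did not pass, with a median of 1.64 (camera adjusted p = 6.02e-04). Of the 11 exocrine genes alone, chosen after seeing the data, 10 rose, 0 fell and 1 did not pass (camera adjusted p = 1.64e-04). CELA1, an elastase gene, rose from 22.9 ± 12.1 to 200.4 ± 53.1 (3.15 ± 0.35), and ctrl, a chymotrypsin-like protease gene, by 3.84 ± 0.66. Of 18 kidney and gut epithelium genes, 6 rose, 1 fell and 11 did not pass (camera adjusted p = 0.0226), among them the intestinal cadherin gene cdh17 (2.91 ± 0.52) and fabp6 (4.39 ± 0.59), a bile acid binding protein gene. malb (4.64 ± 0.62), the keratin gene krt18a.2 (4.45 ± 0.56) and the cathepsin gene ctsl.1 (4.50 ± 0.57) were also among the largest rises. Of 23 immune genes, 11 rose, 1 fell and 11 did not pass (camera adjusted p = 0.00564), including rag1 (3.24 ± 0.73), the lymphocyte recombinase gene, and csf3r (2.06 ± 0.46). Of 16 endothelial genes, 8 rose, 0 fell and 8 did not pass (camera adjusted p = 0.00564), with flt4 at 2.68 ± 0.42 and sox18 at 1.96 ± 0.38. Of 22 liver genes, 7 rose, 0 fell and 15 did not pass (camera adjusted p = 0.00564), with hpxa, a heme binding protein gene, at 2.32 ± 0.51 and the yolk protein gene vtg3 at 2.69 ± 0.68. Of the 73 genes in the ribosome list, 29 rose, 5 fell and 39 did not pass (camera adjusted p = 0.00564). Without the 9 S6 kinase genes, 27 rose, 0 fell and 37 did not pass (camera adjusted p = 4.73e-04), with rps24 at 1.20 ± 0.21 and rpl22l1 at 1.16 ± 0.17. The early response gene fosb rose by 2.97 ± 0.43.

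Of 14 oocyte genes, 3 rose, 0 fell and 11 did not pass at the high dose (camera adjusted p = 0.254), with zp3b at 89.9 ± 23.4 normalized counts (1.80 ± 0.47). The antioxidant list was not called (camera adjusted p = 0.932), and its test pointed down while its median was 0.05; 7 rose, 10 fell and 41 did not pass. The steroid hormone list (2 rose, 3 fell and 20 did not pass; camera adjusted p = 0.739), the thyroid axis list (3 rose, 3 fell and 14 did not pass; camera adjusted p = 0.89) and the mitochondrial genome list (0 of 13 called; test up, median -0.02, mean 0.03; camera adjusted p = 0.909) did not pass. star (0.50 ± 0.27), sod1 (0.24 ± 0.21), cat (-0.10 ± 0.15), slc5a5 (-0.15 ± 0.34) and dmrt1 (-0.37 ± 0.38) did not pass either. In all, 3248 genes were higher and 3638 lower. Which side was larger depended on the level filter, the scaling and the method. A mean of at least 50 left 1336 higher and 3379 lower, no filter gave 4439 and 3620, and a 2-fold minimum 2649 and 1666. On the recovered reads edgeR called 3845 and 3441 and DESeq2 4105 and 3995. Scaling on genes with a control mean of at least 500, chosen after seeing the data, gave 5700 and 1827. With it the calls of dnmt1 (limma adjusted p = 0.0583) and ddx4 (0.212) were lost, while star and sod1 gained a call. Quantile normalization ended 10 of the 11 list calls, all but that of the pancreas list. A mean of at least 50 ended the meiosis, heat shock, cell cycle and immune calls, leaving out high-dose replicate 2 or 3 that of meiosis, and leaving out high-dose replicate 1 that of the ribosome list.

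**Figure D3:**
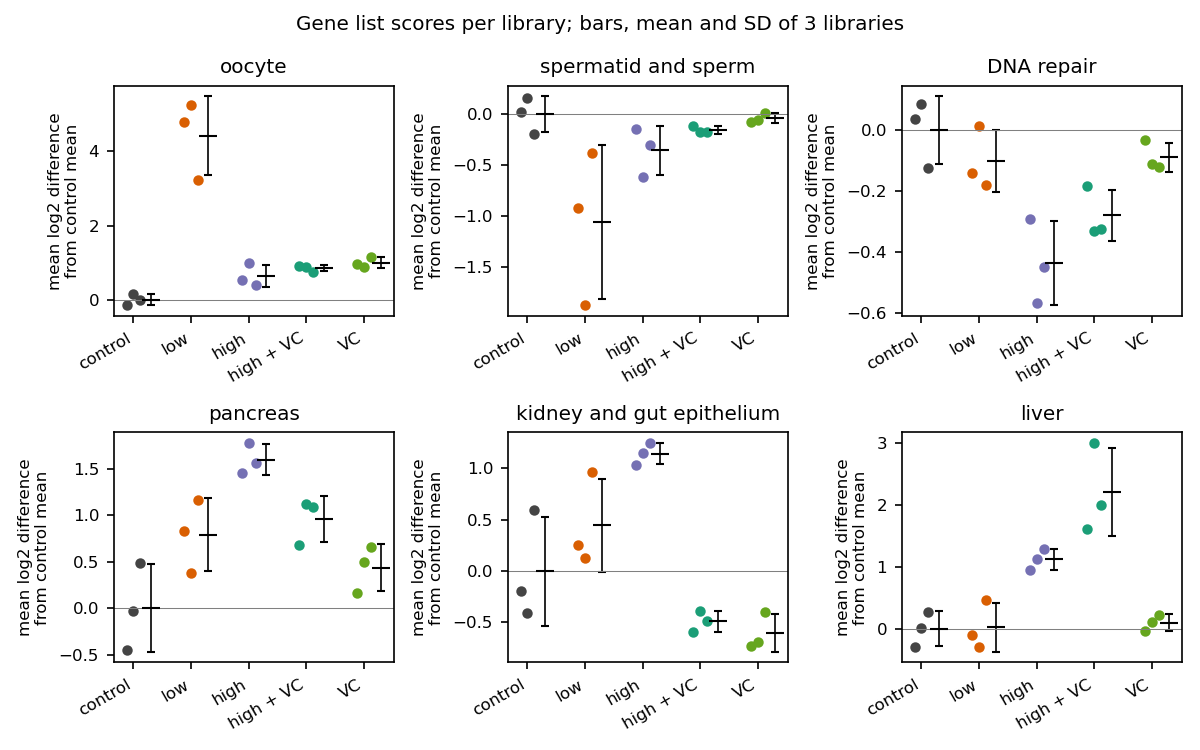
Scores of 6 gene lists in each library, as the mean log2 difference of the list's genes from the control mean (y axis), with groups on the x axis as in the plot of 6 genes. Points are libraries and bars the mean ± SD of 3 libraries; the oocyte score was 3.23 or more in the low-dose libraries, and the liver score reached 3.00 in replicate 2 of the high dose with vitamin C.

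The 2 doses were compared directly, so that a call at 1 dose alone was not read as a difference. Oocyte genes were lower at the high dose: 1 rose, 10 fell and 3 did not pass of 14 (camera adjusted p = 3.89e-06), with zp3b at -6.44 ± 0.47 and bmp15 at -7.06 ± 0.55. No list of this comparison passed with an estimated correlation, the smallest being an adjusted p = 0.484 with an estimated correlation. nqo1 (-6.71 ± 0.51), dnmt1 (-1.55 ± 0.24) and slc5a5 (-1.84 ± 0.34, limma adjusted p = 7.66e-04) were lower as well. Of 38 spermatid and sperm genes, 19 rose, 1 fell and 18 did not pass (camera adjusted p = 3.09e-05), such as spata17 (1.40 ± 0.36) and ropn1l (1.09 ± 0.25). Of 13 mitochondrial genome genes, 9 rose, 0 fell and 4 did not pass (camera adjusted p = 0.00864), such as ND5 (1.26 ± 0.43) and COX1 (1.20 ± 0.35). Of 48 cell cycle genes, 2 rose, 28 fell and 18 did not pass (camera adjusted p = 8.08e-05). Of 37 heat shock and protein folding genes, 2 rose, 18 fell and 17 did not pass (camera adjusted p = 7.69e-04), and of 22 liver genes, 10 rose, 0 fell and 12 did not pass (camera adjusted p = 0.00649), a call that quantile normalization ended, as it did 6 other list calls of this comparison, and a mean of at least 50 ended 4. lhcgr was higher at the high dose by 1.69 ± 0.31, gsdf, a Sertoli cell factor gene, by 0.85 ± 0.24, star by 0.84 ± 0.27, fshr by 0.74 ± 0.24, the synaptonemal complex gene sycp1 by 1.20 ± 0.36, plppr3a by 3.86 ± 0.65, ctsl.1 by 3.38 ± 0.57 and slc12a3 by 2.78 ± 0.61. Of 30 lists, camera called 6 up and 6 down. In all, 3976 genes were higher and 4636 lower at the high dose. Quantile normalization turned this balance, with 4539 higher and 3579 lower, as did no level filter (5323 and 4665) and scaling on genes with a control mean of at least 500 (4677 and 3897), while a mean of at least 50 left 1966 and 4244. Without low-dose replicates 1 and 2, 1031 were higher and 1772 lower, and the calls of spata17, ropn1l, ND5, COX1, gsdf, star, fshr and sycp1 were lost. Without low-dose replicate 2 alone, that of the mitochondrial genome list was. With only these 2 groups in the fit the total fell from 8612 to 2568. Then 9 of the 18 called genes named in the text for this comparison lost their call.

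The fold changes of the 2 doses against the same controls correlated across genes with a Pearson r of 0.441, against 0.4996 for simulated unchanged groups set on those controls. Their covariance was 0.647, against 0.069 simulated. The doses shared 1052 higher and 2034 lower calls, where independent lists of these sizes would share 808 and 834. The covariance is above what the shared controls give in simulation, while for the shared calls the 3 controls cannot be split, so part of that excess may come from them.

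The high dose with vitamin C was compared with the high dose alone to ask what differed when vitamin C was added. Camera called the kidney and gut epithelium list lower with vitamin C, with part of its genes called, a call lost at an adjusted p = 0.299 with an estimated correlation. slc12a3 stood at 2128 ± 780.0 normalized counts at the high dose and at 34.9 ± 3.07 with vitamin C (log2 fold change -5.82 ± 0.61, limma adjusted p = 1.05e-04), and ca15b, a carbonic anhydrase gene, changed by -6.23 ± 0.62. Several blood plasma protein genes were higher: complement gene c3-1 (ENSORLG00000011267) went from 71.0 ± 23.7 to 1827 ± 1577 (4.39 ± 0.47, limma adjusted p = 1.53e-04), with 840.0, 3647 and 996 in replicates 1, 2 and 3. canx, a chaperone gene, went from 285 ± 63.6 to 743 ± 89.6 (1.40 ± 0.20), against 867 ± 93.6 in the controls.

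Of 18 kidney and gut epithelium genes, 1 rose, 6 fell and 11 did not pass (camera adjusted p = 1.30e-04; adjusted p = 0.299 with an estimated correlation, the smallest of the 30 lists here, none of which passed). The score of this list averaged 1.14 ± 0.105 at the high dose, -0.49 ± 0.102 with vitamin C added and -0.60 ± 0.183 with vitamin C alone. In the controls it was -0.19 and -0.41 in replicates 1 and 2 and 0.60 in replicate 3. cdh17 changed by -4.37 ± 0.52, fabp6 by -3.80 ± 0.59, malb by -5.57 ± 0.62, krt18a.2 by -5.09 ± 0.56 and the calcium binding protein gene S100P by -4.49 ± 0.60. Of 22 liver genes, 7 rose, 0 fell and 15 did not pass (camera adjusted p = 0.00197), led by the apolipoprotein genes apoa2 (4.29 ± 0.52) and apoa1b (3.36 ± 0.44) and the fibrinogen gene fgb (3.76 ± 0.58). Of 82 epigenetic enzyme genes, 10 rose, 0 fell and 72 did not pass (camera adjusted p = 0.00312), with KMT2E at 1.02 ± 0.24 and kdm5c at 0.67 ± 0.15. Of 62 DNA repair genes, 14 rose, 0 fell and 48 did not pass (camera adjusted p = 0.0214), with exo1 at 0.86 ± 0.18 and the end joining ligase gene lig4 at 0.87 ± 0.16. Of 37 heat shock and protein folding genes, 5 rose, 0 fell and 32 did not pass (camera adjusted p = 0.0232), with sel1l at 0.80 ± 0.16. The list of p53 and apoptosis genes was not called (camera adjusted p = 0.999): of its 41 genes, 4 rose, 1 fell and 36 did not pass. Of these, mdm2 was higher by 0.999 ± 0.19, and BAX went from 49.6 ± 11.6 to 98.6 ± 9.69 normalized counts (limma adjusted p = 0.0119).

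Of 74 nuclear oxidative phosphorylation genes, 10 rose, 12 fell and 52 did not pass (camera adjusted p = 0.0323), with ndufa4b at -1.90 ± 0.26 and NDUFS1 at 0.92 ± 0.19. Of the 73 genes in the ribosome list, 4 rose, 8 fell and 61 did not pass (7 rose and 25 fell adjusted over the list alone; camera adjusted p = 0.0232). Without the 9 S6 kinase genes, 2 rose, 8 fell and 54 did not pass (camera adjusted p = 0.00266), with rps24 at -0.90 ± 0.21. Of 13 blood genes, 1 rose, 2 fell and 10 did not pass (camera adjusted p = 0.0214), with slc4a1a, the red cell anion exchanger gene, at -2.17 ± 0.47. Of 16 endothelial genes, 0 rose, 2 fell and 14 did not pass (camera adjusted p = 0.0232), with fli1 at -1.09 ± 0.23, and of 15 pancreas genes, 0 rose, 1 fell and 14 did not pass (camera adjusted p = 0.0323; 0.0294 for the 11 exocrine genes). The fatty acid desaturase gene fads2 (ENSORLG00000006358) changed by -1.97 ± 0.22 and star by -1.07 ± 0.27 (limma adjusted p = 0.0212), a call lost without high-dose replicate 3 or without replicate 2 or 3 of the high dose with vitamin C. ddx4 was higher by 0.63 ± 0.18 (limma adjusted p = 0.0397), a call lost with any of the 6 libraries left out and with the replicate block (limma adjusted p = 0.0556). The meiosis (camera adjusted p = 0.745), spermatid and sperm (0.167), immune (0.745) and antioxidant (0.745) lists did not pass, and 0 of 38 spermatid and sperm genes were called by limma. With the low-dose libraries left out of the fit, chosen after seeing the data, 12 of these 38 rose and 0 fell. The immune test pointed up while its median was -1.2e-05. dnmt1 (0.54 ± 0.24) and dmrt1 (1.15 ± 0.38, limma adjusted p = 0.0617) did not pass, but did with the low-dose libraries left out of the fit (limma adjusted p = 0.0124 and 4.72e-04). With the replicate block dmrt1 passed (limma adjusted p = 0.0486). amh (ENSORLG00000015951; 0.48 ± 0.27) did not pass.

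In all, 1376 genes were higher and 469 lower with vitamin C, and 2064 and 308 with TMM. The share of rises was smaller with DESeq2 (2062 and 1631), with only these 2 groups in the fit (2050 and 1092) and without the low-dose libraries (2962 and 2225). The larger side turned with scaling on genes with a control mean of at least 500, which gave 787 higher and 963 lower and ended the ddx4 call (limma adjusted p = 0.071). The replicate block left 1184 higher and 404 lower. Leaving out high-dose replicate 2, or replicate 2 or 3 of the high dose with vitamin C, left 559, 649 and 560 calls, and leaving the low-dose libraries out of the fit gave 5187. Over these 6 libraries, 48 of the 83 called genes that the naming rule picked lost their call with at least 1 library left out, as did 6 of the 10 list calls, all but those of the kidney and gut epithelium, liver, epigenetic enzyme and blood lists. Quantile normalization ended the DNA repair, epigenetic enzyme, heat shock, endothelial, pancreas and ribosome calls. A mean of at least 50 ended the DNA repair, epigenetic enzyme, heat shock, endothelial, pancreas and blood calls, and no level filter the oxidative phosphorylation, endothelial, pancreas and ribosome calls. TMM ended those of the oxidative phosphorylation and ribosome lists.

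Of the 3248 genes higher at the high dose than in controls, 411 were called lower with vitamin C than at the high dose, and 365 were still called higher than in controls. Of the 3638 genes lower at the high dose, 1239 were called higher with vitamin C and 205 were still called lower than in controls. The median log2 fold change against control of the higher genes was 1.69 at the high dose, 0.86 with vitamin C added and 0.37 with vitamin C alone, and that of the lower genes was -0.96, -0.39 and -0.25. Because these genes were picked for their change at the high dose, a smaller change in other libraries is partly a return from that choice.

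The held-out score, which avoids that choice, was 2.18 ± 0.444 at the high dose and 1.02 ± 0.141 with vitamin C added, 47.0% of the high-dose value (mean ± SD, n = 3). It was 0 ± 0.461 in the controls, 0.864 ± 0.0487 at the low dose (1.43 ± 0.251 with its genes chosen without the low-dose libraries) and 0.589 ± 0.206 with vitamin C alone. The score of the high dose with vitamin C lay below the high dose and above the controls in 3 of 3 libraries (exact 2-sided permutation p = 0.1 for each comparison). That is the smallest p that 3 libraries against 3 can give. Control replicate 3 had a score of 0.531, against -0.229 and -0.302 in the other controls.

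**Figure D4:**
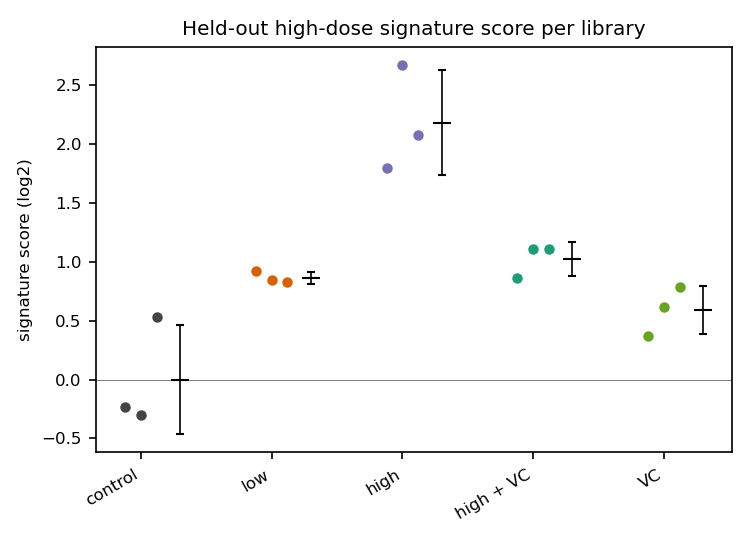
Held-out high-dose score per library (y axis, log2 units from the control mean), with groups on the x axis as in the plot of 6 genes. Points are libraries and bars the mean ± SD of 3 libraries; the high-dose libraries lay at 1.80 to 2.67 and those with vitamin C added at 0.862 to 1.11.

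The high dose with vitamin C was then compared with control to ask what still differed. Plasma protein genes made by liver led the rises. apoa2 (ENSORLG00000024993) went from 9.18 ± 3.08 to 846 ± 722 normalized counts (log2 fold change 6.10 ± 0.52, limma adjusted p = 1.58e-05) and c3-1 from 25.5 ± 14.5 to 1827 ± 1577 (5.91 ± 0.47). fgb (5.62 ± 0.58), fga (5.02 ± 0.57), the complement genes cfbl (5.28 ± 0.59) and c9 (5.16 ± 0.67) and apoa1b (4.20 ± 0.44) were higher too, and these 7 calls held with any 1 library left out. The rise was uneven: the liver list held 0.0454%, 0.149% and 0.0599% of reads in replicates 1, 2 and 3 of the high dose with vitamin C. Whether liver tissue carried along in dissection gave this rise was not tested. Of 22 liver genes, 8 rose, 0 fell and 14 did not pass (13 rose and 0 fell adjusted over the list alone; camera adjusted p = 5.03e-15; adjusted p = 0.115 with an estimated correlation, a value that no list of this comparison went below). Of 23 immune genes, 3 rose, 0 fell and 20 did not pass (13 rose and 0 fell adjusted over the list alone; camera adjusted p = 7.49e-07; adjusted p = 0.115 with an estimated correlation), with the lysozyme gene lyz at 4.56 ± 0.84. Of 15 pancreas genes, 2 rose, 0 fell and 13 did not pass (camera adjusted p = 9.21e-05; 1.10e-05 for the 11 exocrine genes), with CELA1 at 1.92 ± 0.35. Of 14 oocyte genes, 3 rose, 0 fell and 11 did not pass (camera adjusted p = 0.00397), with zp3b at 138 ± 28.7 normalized counts (2.43 ± 0.47) and zar1 at 2.20 ± 0.47. nqo1 changed by 2.52 ± 0.51 and ptgdsb.1 by 1.49 ± 0.31. Of 28 interferon and inflammation genes, 2 rose, 0 fell and 26 did not pass (camera adjusted p = 0.0387).

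Of 30 lists, camera called 7 up and 5 down. Among those down, the DNA repair list (median -0.27, camera adjusted p = 1.47e-05), the meiosis list (median -0.39, 5.97e-04), the cell cycle list (median -0.30, 5.97e-04) and the epigenetic enzyme list (median -0.20, 0.00377) were lower by camera, with few single genes called in the fit of all 15 libraries. These 4 calls were lost at an adjusted p = 0.528, 0.578, 0.578 and 0.546 with an estimated correlation. Of 62 DNA repair genes, 0 rose, 1 fell and 61 did not pass; of 19 meiosis genes, 0 rose, 0 fell and 19 did not pass. Of 48 cell cycle genes, 0 rose, 2 fell and 46 did not pass, with cdk2 at -0.78 ± 0.19. Of 82 epigenetic enzyme genes, 0 rose, 2 fell and 80 did not pass, namely ezh2 (-0.82 ± 0.19) and kdm5c (-0.60 ± 0.15). Without the low-dose libraries in the fit, an alternative chosen after seeing the data, more single genes fell: 10 of 62 DNA repair, 8 of 19 meiosis, 9 of 48 cell cycle and 16 of 82 epigenetic enzyme genes. Then 0, 0, 3 and 1 rose. The germ cell small RNA genes piwil2 (-0.82 ± 0.17) and tdrd9 (-0.84 ± 0.20), BIRC6 (-1.56 ± 0.33), the malic enzyme gene me2 (-1.54 ± 0.31), RAI2 (-1.48 ± 0.37) and the keratin gene krt5 (-2.52 ± 0.57) were lower. piwil2 and tdrd9 belong to the spermatogonia list of 22 genes, which was not called and had a mean score of 0.219 ± 0.0395 here. amh (ENSORLG00000015951) stood at 6143 ± 1549 against 12243 ± 2388 in controls (limma adjusted p = 0.0509, not called), and ddx4 at 13006 ± 2021 against 12819 ± 891.

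In all, 419 genes were higher and 224 lower, and 538 and 127 with TMM. The larger share of rises depended on the fit: with only these 2 groups in it 1735 were higher and 1969 lower, without the low-dose libraries 1402 and 1561, and DESeq2 called 1003 and 953. Leaving out control replicate 1 or 2, or replicate 2 or 3 of the high dose with vitamin C, left 66, 71, 45 and 49 calls, while leaving out control replicate 3 gave 1137 and leaving the low-dose libraries out of the fit 2963. Of the 47 called genes that the rule picked, 40 lost their call with at least 1 library left out. With quantile normalization the DNA repair, epigenetic enzyme and cell cycle list calls were lost, and leaving out control replicate 3 or using no level filter ended that of the interferon and inflammation list.

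Vitamin C alone was compared with control as the background of the combined treatment. In the fit of all 15 libraries 54 genes were higher and 18 lower. DESeq2 called 135 and 122, the fit with only these 2 groups 394 and 277, and that without the low-dose libraries 186 and 120. Among the rises were genes that were also high at the low dose: alv went from 27.8 ± 0.688 to 294 ± 73.5 normalized counts (3.33 ± 0.47, limma adjusted p = 0.00568), and zar1 (3.11 ± 0.47), zp3f.1 (3.07 ± 0.63), zp3b (2.48 ± 0.47), slc7a6 (3.14 ± 0.56), ctss (3.06 ± 0.61) and nqo1 (2.95 ± 0.51) were higher. trhrb, a thyrotropin-releasing hormone receptor gene, went from 154 ± 28.4 to 12.9 ± 1.28 (-3.47 ± 0.56), and evpla (-2.69 ± 0.39), gucy2cb (-2.20 ± 0.44), the dynein gene DYNC1H1 (-1.61 ± 0.32) and keap1a (-1.42 ± 0.25), a sensor gene of oxidative stress, were lower. Of 30 lists, camera called 5 up and 4 down. Of 14 oocyte genes, 3 rose, 0 fell and 11 did not pass (camera adjusted p = 3.12e-05). No list of this comparison passed with an estimated correlation, the smallest being an adjusted p = 0.46 with an estimated correlation. The mitochondrial genome list had a median of -0.69 (camera adjusted p = 2.61e-05; 0 of 13 genes called by limma), and the epigenetic enzyme list one of -0.18 (3.92e-04; 0 of 82 called). Without the low-dose libraries in the fit, 2 of the 13 mitochondrial genome genes fell. The antioxidant list (camera adjusted p = 0.796) and the list of vitamin C transport and collagen genes (camera adjusted p = 0.56) did not pass, and neither did ddx4 (0.49 ± 0.18) or amh (ENSORLG00000015951; -0.32 ± 0.27). The calls were not stable: without vitamin C replicate 1, 2 or 3 they numbered 16, 25 and 8, without control replicate 1 or 2 they numbered 21 and 17, without the low-dose libraries in the fit 306, and all 16 called genes that the rule picked lost their call with at least 1 library left out.

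Within fish given vitamin C, the high dose was set against vitamin C alone, which shares no library with the high dose against control. Several liver plasma protein genes were higher. c3-1 went from 35.9 ± 4.67 to 1827 ± 1577 normalized counts (5.30 ± 0.47, limma adjusted p = 3.33e-05), apoa2 from 17.8 ± 8.37 to 846 ± 722 (5.26 ± 0.52) and fgb from 6.08 ± 0.314 to 299 ± 256 (5.08 ± 0.58). cfbl (4.46 ± 0.59), fga (4.14 ± 0.57), c9 (4.14 ± 0.67), apoa1b (3.97 ± 0.44), tbt-bp1 (4.20 ± 0.66) and the lipid carrier gene apoeb (1.55 ± 0.26) were higher. Liver tissue carried along in dissection was not tested as a source here either. Of 22 liver genes, 6 rose, 0 fell and 16 did not pass (13 rose and 0 fell adjusted over the list alone; camera adjusted p = 2.25e-23), and this list alone, of all lists in the 8 contrasts, passed with an estimated correlation (adjusted p = 0.0349 with an estimated correlation). Of 30 lists, camera called 8 up and 4 down, among them the immune list (median 0.63, camera adjusted p = 1.10e-05), the list of early response genes (median 0.50, 9.91e-06) and the cell cycle list (median -0.25, 1.84e-05), each with 0 members called by limma. Without the low-dose libraries in the fit, 3 of 23 immune genes and 2 of 22 early response genes rose. In all, 48 genes were higher and 0 lower, where DESeq2 on the recovered reads called 164 higher and 9 lower. Without replicate 1 or 2 of the high dose with vitamin C the calls numbered 126 and 20, and without vitamin C replicate 1, 2 or 3 they numbered 25, 30 and 31, and without the low-dose libraries in the fit 109. Those of c9, tbt-bp1 and apoeb were lost with at least 1 library left out. Across genes, these fold changes and those of the high dose against control correlated with a Pearson r of 0.474 (simulated 0.00128) and a covariance of 0.275. The simulated value treats all libraries and genes as independent. Same-numbered libraries of the high dose with and without vitamin C correlated at 0.361, 0.198 and 0.124, so the 2 comparisons may not be independent.

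The difference between the high-dose responses with and without vitamin C was tested as an interaction. Positive values mean a higher response in the presence of vitamin C, and genes with a positive call are counted as risen. canx had an interaction of 1.65 ± 0.29 on the log2 scale (limma adjusted p = 0.00966), KMT2E of 1.74 ± 0.34, mdm2 of 1.18 ± 0.26, kdm5c of 1.11 ± 0.22, exo1 of 0.96 ± 0.25 and sel1l of 0.93 ± 0.23. c3-1 (3.78 ± 0.67), apoa1b (3.13 ± 0.62) and evpla (3.26 ± 0.55) were higher, and CELA1 (-2.55 ± 0.50), slc4a1a (-2.59 ± 0.67), fads2 (ENSORLG00000006358; -1.92 ± 0.31), rps24 (-1.38 ± 0.29) and uqcrb (-1.32 ± 0.27) lower. star (-1.14 ± 0.38, limma adjusted p = 0.0727) and amh (ENSORLG00000015951; 0.80 ± 0.38) did not pass. Of 30 lists, camera called 5 up and 5 down. Of 82 epigenetic enzyme genes, 9 rose, 0 fell and 73 did not pass (16 rose and 0 fell adjusted over the list alone; camera adjusted p = 1.54e-04). Neither this list nor any other passed here with an estimated correlation (smallest adjusted p = 0.634 with an estimated correlation). Of 62 DNA repair genes, 8 rose, 0 fell and 54 did not pass (camera adjusted p = 0.0103); of 37 heat shock and protein folding genes, 6 rose, 0 fell and 31 did not pass (0.0131); of 22 liver genes, 4 rose, 0 fell and 18 did not pass (0.019). Of the 73 genes in the ribosome list, 2 rose, 9 fell and 62 did not pass (camera adjusted p = 0.0103). Without the 9 S6 kinase genes, 0 rose, 9 fell and 55 did not pass (camera adjusted p = 3.00e-04), and of 74 oxidative phosphorylation genes, 2 rose, 7 fell and 65 did not pass (0.0126). Of 15 pancreas genes, 0 rose, 2 fell and 13 did not pass (camera adjusted p = 0.0127; 0.0143 for the 11 exocrine genes, of which 1 fell), and of 18 kidney and gut epithelium genes, 1 rose, 3 fell and 14 did not pass (0.0328). Quantile normalization ended the calls of the DNA repair, heat shock, pancreas and ribosome lists, and a mean of at least 50 those of the DNA repair, heat shock, pancreas and liver lists. Leaving out 1 library ended the liver, kidney and gut epithelium, oxidative phosphorylation and ribosome calls.

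In all, 996 genes had a positive and 440 a negative interaction, and 506 and 784 with scaling on genes with a control mean of at least 500, which ended the exo1 call (limma adjusted p = 0.0625) and gave one to star (0.0313). Leaving out control replicate 1 or 2 left 135 and 133 calls, high-dose replicate 2 left 440, replicates 2 and 3 of the high dose with vitamin C left 311 and 267, and vitamin C replicates 2 and 3 left 255 and 132, while leaving the low-dose libraries out of the fit gave 5055. Of 79 called genes that the rule picked, 66 lost their call with at least 1 library left out.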

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

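The tests of the oocyte transcripts, that of the rise of other tissues, that of genes with a control mean of at least 100, that of genes under the level filter after thinning and that of scaling on genes with a control mean of at least 500 were chosen only after those results were seen. The other tests were set before their outcome was seen, although thinning itself was chosen after the calls were.

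With each library left out in turn, the count of interaction calls ranged from 132 to 1825. In the main fit, the interaction called 1436 genes as differing in their response to the high dose with and without vitamin C. Of these, 1388 were also called at the high dose against control and 26 in the high dose with vitamin C against vitamin C alone, 1379 had the larger change without vitamin C, and 607 had opposite signs in the 2 comparisons. The interaction holds the libraries of both comparisons, which called 6886 and 48 genes in all. These overlaps therefore follow in part from how it is made up. Of 100 random splits of these 12 libraries, 2 gave as many genes, the real one included. Such splits mix groups that differ, which widens the spread within a group and lowers the calls. They therefore cannot decide whether the interaction calls arose by chance. The highest other split called 2934 genes, more than the real one. It put all 3 controls into 1 group. By the signs of the interaction, it set all 3 high-dose libraries on 1 side and all 3 controls on the other. That split therefore held part of the difference of the high dose against control, which called 6886 genes. For the 2-group contrasts 3 libraries against 3 make 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each. The real counts were 8499 for the low dose against control, 6886 for the high dose against control and 8612 for the high against the low dose. They were 1845 for the high dose with vitamin C against the high dose, 643 for it against control, 72 for vitamin C alone and 48 for the high dose within fish given vitamin C. The highest other split gave 997 genes for the high against the low dose and 0 in each of the other 6 contrasts, so for the high dose with and without vitamin C also 0 in splits that part the same-numbered libraries.

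Oocyte transcripts were high in the low-dose libraries. For ovary libraries under a wrong label, the spermatid and sperm genes were read. They kept 42.5%, 16.8% and 78.3% of their control share of reads in replicates 1, 2 and 3, each above the bound of 10%. That bound was set after the result, and no ovary library was sequenced to show what share an ovary would hold. A wrong label is therefore not decided, least of all for replicate 2. A single source of oocyte RNA in different amounts, such as ovary tissue mixed into the samples, was not told apart from several sources. The log2 ratio of the rise between replicates 2 and 3 had an SD of 0.759 over the oocyte genes, between the bounds of 0.5 and 1 set for the test. These ratios ran from 1.29 for sox3 to 4.27 for ccnb1. Between replicates 1 and 3, a pair the test did not use, they lay closer together, from 1.59 for sox3 to 3.20 for ccnb1. Oocytes formed in the testis at this dose stay open too: 12 of the 14 oocyte genes were higher in every low-dose library, and the high-dose score lay below the low-dose score by a difference of -3.78, which argues only against a response that grows with dose. For the smaller rise in the groups given vitamin C, reads leaking from the low-dose libraries are argued against as the whole cause, because zar1 rose by 2.31% ± 0.434 (SE) of its low-dose rise, bmp15 by 0.358% ± 0.0531 and gdf9 by -0.188% ± 0.201, where a leak needs 1 share for all; how these shares were compared was changed after a first result was seen.

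The genes called higher at the high dose may come from several sources. Unequal depth is argued against as the whole cause, since 86.0% of the 2003 such genes still above the level filter after thinning were called again, and the other 1245 kept a median log2 fold change of 2.05, with a lower quartile of 1.59, where depth needs a median under 0.2; 76.5% of these were called again, under a first bound of 80, so how they were judged was changed after that was seen. An even background of reads cannot be told apart for low genes, as 56.6% of 3101 genes with a control mean of 1 to 5 were above it in all 3 high-dose libraries, between the bounds of 50 and 90. High-dose replicate 1, with 3.21 M reads, can miss low genes by sampling, so the bound of 90 was hard to reach even with such a background. High-dose replicate 2 had reads on 22931 of 23028 genes at 12.2 M reads. The deepest library, replicate 1 of the high dose with vitamin C, had reads on 22650 at 21.3 M. For the 571 genes with a control mean of at least 100 an even background is argued against. Their median rise was 47.9 times that of the low genes. A call at that level already needs a larger rise than the low genes had, so this ratio was in part set by the choice of called genes. For a lower share of testis cells that raises other tissues alike, the pancreas score was set against that of smooth muscle and peritubular cells. The pancreas score was higher by at least 1.13 in each high-dose library, against an SD of at most 0.167, and by at least 1.62 without its islet hormone genes. These lists were picked as the highest and the lowest of their kind in these libraries. A gap was thus built in, and this cause is not decided. Neighbouring tissue carried along in dissection, to a different extent per tissue, and a response of the testis to perchlorate both stay open.

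For the genes called lower at the high dose, a shift of the size factors is left open by their median log2 fold change of -0.96 against -0.37 in the 4696 genes with a control mean of at least 500, since genes picked as lower lie below under any shift. With all libraries scaled on those 4696 genes, 50.2% stayed called lower, just over the bound of 50, which argues against a shift as the whole cause for these 1827 genes only. The same scaling raised the genes called higher from 3248 to 5700, so a shift could account for the rest, for part of the size and for the balance of the 2 sides. A response to perchlorate and a change in the share of germ cells stay open as untested.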

How the results depend on the processing

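Leaving out the low-dose libraries, leaving out low-dose replicates 1 and 2, thinning, and taking genes out of the ribosome and pancreas lists, and scaling on genes with a control mean of at least 500 were chosen only after the results were seen. Counts of calls depended on the fit. With only the groups of a contrast in the fit, they were 3250 for the low dose, 2568 for the high against the low dose, 3142 for the high dose with vitamin C against the high dose, 3704 for it against control, 671 for vitamin C alone, 215 for the high dose within vitamin C and 5055 for the interaction. Without the low-dose libraries they were 5187, 2963, 306, 109 and 5055 for the last 5 of these. With DESeq2 on recovered reads, these 5 gave 3693, 1956, 257, 173 and 3133. An adjusted p under 0.1 gave 3105, 1640, 137 and 2953 for the high dose with vitamin C against the high dose and against control, vitamin C alone and the interaction. A 2-fold minimum gave 5269 for the low dose, 4315 for the high dose, 5610 for high against low and 853 for the high dose with vitamin C against the high dose. For the high dose with vitamin C against control, a mean of at least 50 gave 262, quantile normalization 343 and thinning 365; a mean of at least 50 gave 22 for the high dose within vitamin C, thinning 895 for the interaction, and no trend 39 for vitamin C alone. Without low-dose replicates 1 and 2 the counts were 1213 for the low dose and 2803 for high against low, and dmrt1 there turned to -0.18 from 1.01. The cause was not tested, except that stricter thresholds and filters lower counts by construction.

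With each library left out in turn, the counts ranged from 6117 to 10921 for the low dose, 4672 to 6725 for the high dose, 5954 to 11566 for high against low, 559 to 1613 for the high dose with vitamin C against the high dose, 45 to 1137 for it against control, 8 to 84 for vitamin C alone, 20 to 126 within vitamin C and 132 to 1825 for the interaction. Of the called genes the rule picked, 15 of 135 lost their call for the low dose, 15 of 132 for the high dose, 19 of 136 for high against low and 3 of 9 within vitamin C. Over all groups, 10 of 30 pairs of same-numbered libraries had a correlation over 0.1, and 7 of 15 libraries correlated best with their own number; all 3 pairs did so only for the high dose with and without vitamin C. With the replicate block the counts were 8392, 6738, 8485, 1588, 680, 89, 53 and 1122 in the order above. TMM moved the median of all genes by 0.13 for the high dose with vitamin C against the high dose; quantile normalization moved it from -0.01 to -0.18 for the low dose and from 0.02 to 0.16 for high against low. Of the list calls in the report and in the part after this one, 81 were lost with an estimated correlation, 39 with quantile normalization and 26 with a mean of at least 50. The held-out score of the high dose with vitamin C stayed within 1 SD in each alternative, but that of the low dose went from 39.6% to 71.1% of the high-dose score when its genes were chosen without the low-dose libraries. With the replicate block ddx4 lost its call and dmrt1 gained one for the high dose with vitamin C against the high dose, and kdm5c lost its call for it against control. Without its islet hormone genes the pancreas list lost its call for vitamin C alone (camera adjusted p = 0.0599) and gained one for the low dose (0.045), and without S6 kinase genes the ribosome list gained one for the high dose with vitamin C against control (0.0218). Scaling on genes with a control mean of at least 500 kept every total within 1.5-fold but turned the balance for the high against the low dose, the high dose against control, the high dose with vitamin C against the high dose and the interaction; it gave calls to star and sod1 at the high dose and to dnmt1, cat and sod1 at the low dose, where fshr lost its call. For the high dose with vitamin C against control it ended the calls of kdm5c, cdk2, tdrd9 and RAI2, and for vitamin C alone those of gucy2cb, ctss, zp3f.1 and DYNC1H1. In simulated data 2.99% of genes changed 1.5-fold were recovered, but few genes were changed there, which makes the adjusted threshold strict. At the high dose, 1666 of the 3638 genes called lower fell at least 2-fold, so smaller falls were called too. How many small changes were missed in the real data was not tested.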

Other observations

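The tests of lists without some of their genes were chosen only after the result was seen. The lists were written before the data were examined, and each called list of the 30 that the report leaves out is given here. None of the lists in this part passed with an estimated correlation: the smallest was an adjusted p = 0.292 with an estimated correlation for whole lists, and 0.25 for the 11 exocrine genes within fish given vitamin C. For the high against the low dose, 13 rose, 2 fell and 11 did not pass of 26 hormone receptor genes (camera adjusted p = 0.0398), 12 rose, 2 fell and 9 did not pass of 23 immune genes (0.0152) and 7 rose, 0 fell and 9 did not pass of 16 endothelial genes (0.0133), and these 3 lists were higher. Antioxidant genes (4 rose, 23 fell and 31 did not pass; camera adjusted p = 0.026), DNA repair genes (3 rose, 24 fell and 35 did not pass; 0.0152) and oxidative phosphorylation genes (5 rose, 27 fell and 42 did not pass; 0.0152) were lower as lists. Quantile normalization ended all 6 of these calls, a mean of at least 50 those of the immune, antioxidant, DNA repair and oxidative phosphorylation lists, and no level filter that of the hormone receptor list. For the high dose with vitamin C against control, the early response (median 0.49, camera adjusted p = 5.97e-04) and endothelial lists (median 0.36, 0.0387) were higher, with 1 gene called in each, and the heat shock and protein folding list (median -0.16, 0.0426) lower. Quantile normalization and a mean of at least 50 each ended the endothelial and heat shock calls.

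For vitamin C alone, the immune (median 0.50, camera adjusted p = 0.028), pancreas (median 0.23, 0.028; 0.0599 and no call for the 11 exocrine genes), oxidative phosphorylation (median 0.14, 0.0212) and ribosome lists (median 0.15, 0.0219; 0.17 and 0.00127 without 9 S6 kinase genes) were higher. The kidney and gut epithelium (median -0.40, camera adjusted p = 0.028) and smooth muscle and peritubular lists (median -0.35, 0.0388) were lower. Quantile normalization ended the immune, pancreas and ribosome calls, and a mean of at least 50 the immune, pancreas and smooth muscle calls. With only these 2 groups in the fit, only the oxidative phosphorylation call of these 6 was kept. For the high dose within fish given vitamin C, the Sertoli (median 0.28, camera adjusted p = 0.00965), smooth muscle and peritubular (median 0.37, 8.31e-04), endothelial (median 0.25, 0.0144), pancreas (median 0.67, 0.00322; 4.45e-05 for the 11 exocrine genes) and mitochondrial genome lists (median 0.59, 5.23e-05) were higher. The meiosis (median -0.30, camera adjusted p = 5.18e-05), DNA repair (median -0.18, 2.17e-04) and oxidative phosphorylation lists (median -0.26, 9.91e-06) were lower. Quantile normalization ended the endothelial and DNA repair calls, and a mean of at least 50 the endothelial call. In the interaction, the circadian clock list was higher (median 0.30, camera adjusted p = 0.0446; 3 rose, 0 fell and 28 did not pass) and the blood list lower (median -0.86, camera adjusted p = 0.0381; 1 rose, 3 fell and 9 did not pass). A mean of at least 50 ended both calls, quantile normalization that of the clock list and no level filter that of the blood list. With at least 1 library left out, 6 of the 12 called lists of the high against the low dose lost their call, 3 of 12 for the high dose with vitamin C against control, 6 of 9 for vitamin C alone, 0 of 12 within fish given vitamin C and 6 of 10 in the interaction.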
